A study of Rattus norvegicus with 75 samples.

How the data were processed

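The arrays analysed here are 15 Agilent 1-colour rat arrays: clone 1c of the reprogrammed hepatocytes (1 array), hepatocytes freshly isolated from chimeric livers (2 arrays), and those hepatocytes after 1, 7 and 14 days in culture with or without YAC (2 arrays for each day and condition). The other 60 of the 75 samples of the series were not analysed here, because the values used were matched to samples only through the sample's own deposited file. A further 4 whole-series tables hold 99 columns whose names match no sample label, and they were not used here. The labels do not say whether replicate arrays come from separate cultures or separate host animals, so the p-values may measure technical spread only. Per the labels' protocols, RNA was extracted with miRNeasy and labelled with Cy3 by the Low Input Quick Amp 1-colour kit. Per the file headers, Agilent Feature Extraction 10.7.3.1 subtracted background and removed spatial and multiplicative trends on each array, and the array design was annotated on rn4.

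The deposited value used is the background-subtracted and detrended intensity of each spot per the file headers (gProcessedSignal), on a linear scale. Each array has 62976 spots, of which 58717 carry gene probes, for 30367 probes. Spots of the same probe were averaged on the log2 scale after leaving out spots marked as non-uniformity or population outliers. For 33 probe values on 1 array each, all spots were marked, and the mean of all spots was kept. Each array's log2 values were then reduced by that array's 75th percentile, which lay between a signal of 1341 and 3978 over the 15 arrays. Between 62.9% and 74.4% of the probes of an array were well above background by the software's own mark.

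Probes were named through their RefSeq accession, without its version, in the supplied RefSeq gene table (assembly GRCr8, used for names only). This gave 18750 probes a current symbol, covering 15709 genes, of which 2770 had several probes. The other 11617 probes kept the systematic name in the file. A gene with several probes was represented by the probe with the highest mean signal, giving 26650 genes and unnamed transcripts. A gene was tested when its probe was well above background on all arrays of at least 1 group, and 20791 were tested, 12740 of them with a symbol. Counts of genes are counts of these, unnamed transcripts included.

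The choices of test, filter, gene lists, named-gene rule and alternatives were fixed before the data were examined. All comparisons come from 1 limma fit (lmFit, contrasts.fit, eBayes) over the 15 arrays with a mean per group, 7 residual degrees of freedom and 8.77 in total after moderation. Clone 1c has 1 array, so its comparisons borrow their spread from the other groups. Adjusted p is the Benjamini-Hochberg value over the genes of a comparison, and a gene rose or fell when adjusted p was below 0.05 and the change at least 2-fold. Values after ± are standard errors (SE) of the log2 fold change from limma unless SD is written.

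Gene groups were tested with 18 fixed lists holding 355 members, of which 334 are on the array and 308 were tested: plasma proteins, cytochrome P450, hepatocyte transporters, amino acid and urea enzymes, glucose and bile acid enzymes, hepatocyte transcription factors, biliary genes, progenitor genes, cell cycle, TGF-β and mesenchymal genes, Wnt targets, YAP and SRF targets, acute phase and STAT3 genes, glucocorticoid receptor targets, cholesterol synthesis, and markers of stellate cells and fibroblasts, of endothelium, and of macrophages and leukocytes. The list test is camera of limma with the preset correlation of 0.01, adjusted over 108 tests (18 lists in 6 comparisons), and it was repeated with the correlation estimated within each list. Of the 108 tests 59 passed at the preset correlation. None, 0 of 108, passed with an estimated correlation, where the lowest adjusted p was 0.21 and 21 tests had an unadjusted p below 0.05. A count of list members adjusted over the list alone differed from the count adjusted over all genes in 8 of 108 cases, by at most 1 gene.

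The genes named for a comparison follow a fixed rule: the 6 largest rises and 6 largest falls among called genes with a symbol whose arrays do not overlap between groups, up to 4 called members of each list (the 2 largest if none was called), and Alb, Afp, Krt19, Sox9, Epcam, Hnf4a, Cyp1a2, Tat, Mki67 and Axin2 in every comparison. Some genes under this rule are not reported here. When the dimmer group was not well above background on any array, the fold is given as "at least". That bound compares the bright group's mean with a raised mean of the dim group. Each dim array was raised to the lowest signal among its probes well above background, wherever the probe itself lay lower. Where the probe already lay above that signal on the dim arrays, the bound equals the measured fold. The bound is therefore not a lower limit on the true fold, and a different background correction can give a smaller fold. When neither group was well above background on any array no fold is given.

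Per the file headers the arrays lie on 2 slides: clone 1c, fresh and day 1 cells on 1 slide (7 arrays), day 7 and day 14 cells on the other (8 arrays). The YAC comparisons and fresh cells against clone 1c stay within a slide. Day 14 with YAC against fresh cells or against clone 1c is aliased with slide, and a slide block could not be fitted. The fit was repeated with quantile normalisation, with no filter on dim genes, with the mean of all probes of a gene, and with an intensity trend and robust prior in eBayes. It was also repeated with normexp background correction (offset 50, on median instead of mean foreground), with a replicate block, and with each array left out in turn. Scaling on the 10 E1A spike-in probes and a crossed replicate block were added after the results were seen, as were the differences of the YAC effect between days. The spike-in reference itself differed between replicate arrays. Relative to the spike-in median, the 75th percentile stood at log2 1.99 and 1.38 on the 2 day 14 arrays without YAC. On the 2 fresh arrays it stood at 0.75 and 1.09. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

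A simulation planted changes in 50 genes per fold among 20791 genes, with independent noise of each gene's fitted spread. It had 1 mean per gene for all groups, no background floor and far fewer changed genes than most comparisons here. Its rates may therefore not carry over to the data. For the YAC comparisons, 32% to 40% of genes changed 2-fold were recovered, 86% to 90% at 3-fold and 98% to 100% at 8-fold. For day 14 with YAC against fresh cells recovery was 44% at 2-fold and 88% at 3-fold. Fresh cells against clone 1c gave 36% and 90%, and day 14 with YAC against clone 1c gave 44% and 78%. Between 1 and 6 unchanged genes were called per comparison and 0 planted genes were called in the wrong direction.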

Results

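The livers came from chimeric mice, whose rat cells derive from transplanted reprogrammed hepatocytes. Whether RNA of the mouse host hybridised to these rat arrays was not tested. Hepatocytes isolated from these livers were compared with and without YAC after 1, 7 and 14 days in culture, with 2 arrays in each group. They were also compared with clone 1c, a clone of the reprogrammed cells measured on 1 array, and with the freshly isolated cells (2 arrays). Clone 1c is written as such throughout, and each YAC comparison gives cells with YAC relative to cells without it on the same day.

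YAC after 1 day shows what the compounds change at the start of culture. Several genes that respond to the actin cytoskeleton fell with YAC. Ankrd1, a target of YAP in mechanical signalling, fell 16.5-fold (log2 -4.04 ± 0.20, n = 2 arrays per group). Tagln, which encodes an actin-binding protein, fell at least 10.1-fold as measured (log2 -3.34 ± 0.40), a bound that does not hold with normexp. Vim, the intermediate filament of mesenchymal cells, fell 6.45-fold (log2 -2.69 ± 0.10). Pmepa1, a feedback inhibitor induced by TGF-β, fell 6.26-fold (log2 -2.65 ± 0.32). Among single liver genes Cyp2c24, a cytochrome P450, rose 51.1-fold (log2 5.67 ± 0.31). The sterol exporter Abcg5 rose 8.79-fold (log2 3.14 ± 0.33). Axin2, a feedback target of Wnt signalling, rose 4.98-fold (log2 2.32 ± 0.41), a call lost when either of 2 arrays was left out (adjusted p = 0.055 and 0.065). The kidney injury marker Havcr1 fell 20.1-fold (log2 -4.33 ± 0.32), the natriuretic peptide gene Nppb 13.8-fold (log2 -3.79 ± 0.22), and the apoptosis inhibitor Birc7 at least 29.2-fold (SE 0.71).

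By list after 1 day, 5 of the 17 YAP and SRF targets fell with YAC and 0 rose (Ankrd1, Tagln, Ccn1 at log2 -1.43 ± 0.16 and Flna; median -0.67, adjusted p = 1.2e-07, adjusted p = 0.21 with an estimated correlation). Of 19 TGF-β and mesenchymal genes 6 fell and 0 rose, Ltbp2 (at least 9.17-fold, SE 0.32) and Tgfb2 (log2 -1.32 ± 0.15) among them (median -0.33, adjusted p = 0.000322, 0.21 with an estimated correlation). Transcription factors of hepatocytes had 3 risers of 17 and 0 fallers: the xenobiotic receptor Nr1i3 (log2 1.91 ± 0.13), the lipid regulator Creb3l3 (log2 1.53 ± 0.10) and the bile acid sensor target Nr0b2 (log2 1.04 ± 0.24) (median 0.58, adjusted p = 4.6e-08, 0.21 with an estimated correlation). Glucose and bile acid enzymes had 5 risers of 18 and 0 fallers, 6 risers when adjusted over the list alone (median 0.45, adjusted p = 1.8e-05, 0.24 with an estimated correlation). Among them Baat, which conjugates bile acids, rose 3.56-fold (log2 1.83 ± 0.25) and Cyp7a1, the entry enzyme of bile acid synthesis, rose at least 8.41-fold (SE 0.62), a call lost with normexp (log2 0.83, adjusted p = 0.34).

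Smaller shifts after 1 day were a rise of 1 of 17 transporters, Abcg5 (median 0.52, adjusted p = 9.1e-07, 0.24 with an estimated correlation). Of 22 amino acid and urea enzymes 1 rose (Bhmt; median 0.41, adjusted p = 6.3e-05, 0.35 with an estimated correlation). Of 23 cytochrome P450 genes 2 rose (Cyp2b2 and Cyp2b3, 3 adjusted over the list alone; median 0.26, adjusted p = 0.00124, 0.41 with an estimated correlation). None of the 20 plasma proteins rose or fell by limma (5 had unadjusted p below 0.05), with a list median of 0.12 (adjusted p = 0.0149, 0.53 with an estimated correlation). For cholesterol synthesis, 2 of 18 enzymes rose, Sqle among them (log2 1.06 ± 0.21), and 0 under spike-in scaling. The list median was 0.36 (adjusted p = 3.4e-05, 0.34 with an estimated correlation). Biliary genes split, with Ggt1 and Sctr up and Sox4 (log2 -1.92 ± 0.11) and Cldn4 (at least 3.66-fold, SE 0.27) down (median -0.11, adjusted p = 0.22). Nothing was called in limma among the 13 progenitor genes (2 at unadjusted p below 0.05; adjusted p of the list = 0.27) or the 23 cell cycle genes (1 at unadjusted p below 0.05; adjusted p of the list = 0.46). Macrophage and leukocyte markers had Lyz2 up and Cd14 down (adjusted p = 0.34). Stellate and fibroblast markers had Rgs5 up and Bgn down (adjusted p = 0.94), and endothelial markers no call (1 at unadjusted p below 0.05, adjusted p of the list = 0.13). Wnt targets had only Axin2 up (adjusted p = 0.085). Glucocorticoid receptor targets had the metallothioneins Mt1 and Mt2A up and Sgk1 down (adjusted p = 0.13). Acute phase and STAT3 genes had 1 faller, Timp1, with a median of 0.07, a mean of -0.01 and adjusted p = 0.93.

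YAC after 1 day changed 408 genes, 156 up and 252 down (200 with normexp, 244 under spike-in scaling). Alb (log2 0.12 ± 0.08, adjusted p = 0.44), Afp (log2 0.15 ± 0.14, adjusted p = 0.60) and the proliferation marker Mki67 (log2 -0.06 ± 0.20, adjusted p = 0.90) did not pass, and neither did Sox9, Tat or Cyp1a2. Hnf4a, the central transcription factor of hepatocytes, was higher by less than 2-fold (log2 0.60 ± 0.07, adjusted p = 0.0013). Calls of Tagln, Ltbp2 and Cldn4 after 1 day end with normexp, where the log2 changes are -0.93, -0.87 and -0.34. The "at least" folds given above for these genes therefore do not hold under normexp. Under spike-in scaling Sqle, Nr0b2, Mt1 and Lyz2 keep their folds (log2 1.12, 1.10, 1.29 and 1.20) with adjusted p from 0.071 to 0.076, and Cd14 is at -0.96 (adjusted p = 0.14).

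The comparison after 7 days shows which genes differed with YAC midway through the culture. Several liver detoxification genes rose with YAC, Cyp3a23-3a1 at least 1591-fold (SE 0.46). Cyp2e1, which oxidises ethanol, rose at least 157-fold (log2 7.30 ± 0.41) and the glucuronyl transferase Ugt2b1 72.3-fold (log2 6.18 ± 0.28; n = 2 arrays per group). The urea cycle enzyme Cps1 rose at least 53.3-fold (SE 0.53), the clotting factor F9 at least 14.4-fold (SE 0.46). The plasma protein precursor Ambp rose 13.8-fold (log2 3.79 ± 0.26) and the bile salt export pump Abcb11 at least 14.6-fold (log2 3.87 ± 0.24). The keratin gene Krt17 fell 56.1-fold (log2 -5.81 ± 0.36), Krt7 23.1-fold (log2 -4.53 ± 0.33) and Krt19 7.65-fold (log2 -2.94 ± 0.22). Tagln fell 24.7-fold (log2 -4.63 ± 0.40) and Pmepa1 23.2-fold (log2 -4.54 ± 0.32).

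Among the lists after 7 days, 9 of 20 plasma proteins rose and 0 fell (Ambp, F9, Itih3, Apoc3; median 0.95, adjusted p = 1.5e-13, 0.21 with an estimated correlation). Cytochrome P450 genes had 12 risers of 23 and 2 fallers, Cyp2c23 and Cyp4a3 (median 1.43, adjusted p = 6.5e-05, 0.34 with an estimated correlation). Amino acid and urea enzymes had 7 risers of 22 and 0 fallers, with Tdo2, which degrades tryptophan, at log2 4.12 ± 0.49 and Otc of the urea cycle at log2 2.48 ± 0.27 (median 0.57, adjusted p = 7.5e-08, 0.28 with an estimated correlation). Glucose and bile acid enzymes had 5 risers of 18, such as the glycogen synthase Gys2 (log2 3.61 ± 0.25) and Cyp8b1 (log2 3.07 ± 0.29), and 1 faller, the gluconeogenic Pck1 (median 0.62, adjusted p = 3.4e-05, 0.24 with an estimated correlation). Transporters had 3 risers of 17 and 0 fallers, Abcb11, Abcb4 and Abcg5 (median 0.40, adjusted p = 0.0037, 0.34 with an estimated correlation). Acute phase and STAT3 genes had 7 risers of 20, among them Saa4 (62.8-fold, log2 5.97 ± 0.25) and Orm1 (61.8-fold, log2 5.95 ± 0.21), and 3 fallers, Lcn2, Il1rn and Hamp (median 0.71, adjusted p = 0.00533, 0.24 with an estimated correlation).

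Down after 7 days were 6 of the 17 YAP and SRF targets, 7 adjusted over the list alone, and 0 rose (Tpm2 at log2 -3.67 ± 0.63, Ankrd1 at log2 -2.20 ± 0.20, Myl9, Ccn1; median -0.60, adjusted p = 4.4e-08, 0.21 with an estimated correlation). TGF-β and mesenchymal genes had 4 fallers of 19, Ltbp2, Thbs1, Pmepa1 and Tgfb1 (log2 -1.74 ± 0.19), and Snai2 up without a fold that can be given (median -0.22, adjusted p = 0.00805, 0.21 with an estimated correlation). Biliary genes had 5 fallers of 16, Krt19, Krt7, Spp1, Ggt1 and the tight junction gene Cldn4 (log2 -2.75 ± 0.27), and 0 risers, 1 adjusted over the list alone (median -0.15, adjusted p = 0.00218, 0.28 with an estimated correlation). Progenitor genes had H19 up and Epcam down (log2 -1.03 ± 0.12), with a median of -0.17, a mean of 0.02 and adjusted p = 0.37. No cell cycle gene was called in limma (1 at unadjusted p below 0.05; median -0.15, adjusted p of the list = 0.083), and no cholesterol synthesis gene (2 at unadjusted p below 0.05; median -0.06, adjusted p of the list = 0.46).

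In the remaining lists after 7 days the direction depends on scaling. Hepatocyte transcription factors had Ppara up (log2 1.55 ± 0.17) and Nr0b2 down, with a median of 0.20, -0.03 under spike-in scaling (adjusted p = 0.089). Wnt targets had Axin2 up (log2 1.83 ± 0.41), 2 risers adjusted over the list alone, with a median of 0.22, -0.01 under spike-in scaling (adjusted p = 0.26). Glucocorticoid receptor targets had Zbtb16 and Sult1a1 up, with a median of 0.16, -0.07 under spike-in scaling (adjusted p = 0.16). Macrophage and leukocyte markers had Lyz2 up (median 0.13, -0.10 under spike-in scaling, adjusted p = 0.26). Stellate and fibroblast markers had Reln and Rgs5 up and Des and Bgn down (median 0.00, -0.22 under spike-in scaling, adjusted p = 0.61). Endothelial markers had no call (1 at unadjusted p below 0.05, median 0.05, -0.18 under spike-in scaling, adjusted p = 0.94).

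YAC after 7 days changed 998 genes, 606 with normexp. Of the 998, 534 were up and 464 down (53.5% up, 39.8% under spike-in scaling, which moves the median of all genes from 0.03 to -0.20). Alb (log2 0.26 ± 0.08, adjusted p = 0.062), Hnf4a (log2 -0.22 ± 0.07, adjusted p = 0.058), Mki67 (log2 -0.04 ± 0.20, adjusted p = 0.93), and Sox9 did not pass. Afp was lower by just under 2-fold (log2 -0.97 ± 0.14, adjusted p = 0.0019). Tat was higher by less than 2-fold (log2 0.92 ± 0.22), and Cyp1a2 passed without a fold that can be given. For 1 called gene, Tacc1, another probe was called in the opposite direction. After 7 days Nr0b2, H19, Zbtb16 and Des have adjusted p above 0.05 in at least 1 of the fits without an array, and Epcam is below 2-fold in at least 1. Under spike-in scaling Snai2, Reln and Lyz2 are at log2 0.84, 1.03 and 0.92, with adjusted p of 0.21, 0.063 and 0.11.

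**Figure D1:**
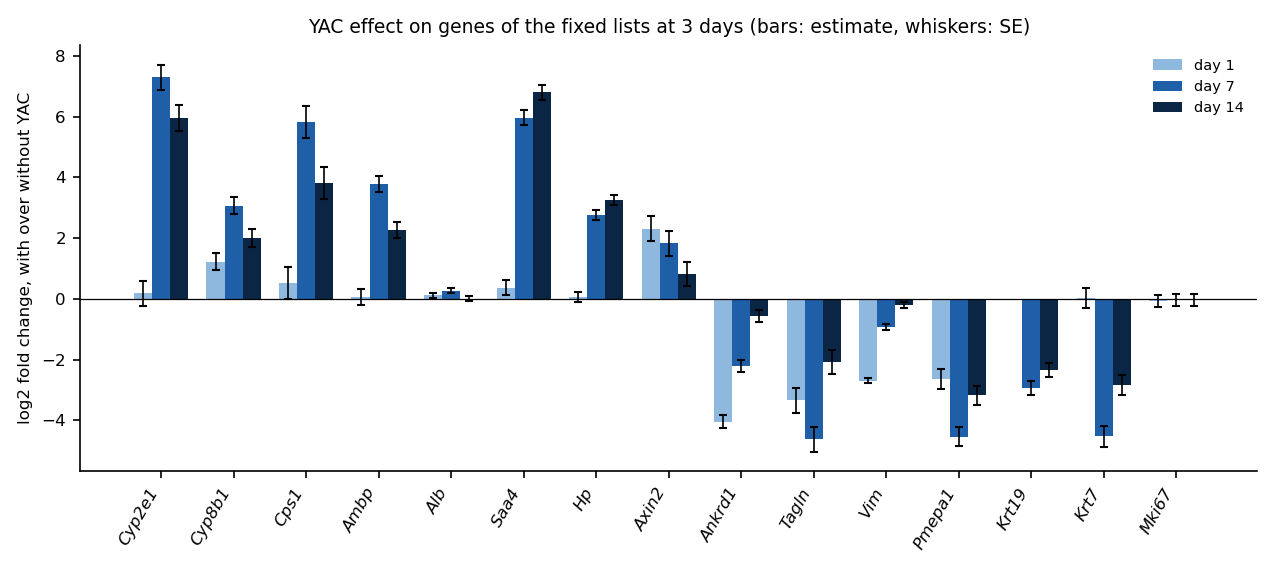
Log2 fold change with YAC relative to without YAC for 15 genes after 1, 7 and 14 days (bars, whiskers are SE from limma, n = 2 arrays per group). Krt19 has no bar after 1 day, when neither group was well above background, and bars against a group not well above background show the measured difference.

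YAC after 14 days shows the state at the end of the culture. The growth factor gene Igf1 rose 171-fold (log2 7.42 ± 0.15; n = 2 arrays per group). The acute phase gene Saa4 rose 112-fold (log2 6.80 ± 0.25), the haptoglobin gene Hp 9.60-fold (log2 3.26 ± 0.16) and Cyp2e1 at least 36.0-fold (SE 0.41). Cps1 rose 14.0-fold (log2 3.81 ± 0.53). Among the largest falls were Gkn2 (at least 269-fold, SE 0.58), which encodes a stomach protein, Tff1 (139-fold, log2 -7.12 ± 0.64), a trefoil factor, and Ms4a8 (132-fold, log2 -7.04 ± 0.22). Cyp3a9 fell 84.5-fold (log2 -6.40 ± 0.21) while Cyp3a23-3a1 of the same family rose 30.1-fold (log2 4.91 ± 0.46).

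List results after 14 days were mixed. Acute phase and STAT3 genes had 5 risers of 20, Saa4, Orm1, Hp, Serpina3n and A2m (log2 4.05 ± 0.45), and 1 faller, Hamp (median 0.68, adjusted p = 6.5e-05, 0.21 with an estimated correlation). Plasma proteins had 3 risers of 20, Apoc3, Ambp (log2 2.26 ± 0.26) and Itih3, 4 adjusted over the list alone, and 1 faller, Apob (median 0.48, adjusted p = 0.0199, 0.53 with an estimated correlation). Cholesterol synthesis had 2 fallers of 18, Idi1 (log2 -1.31 ± 0.25) and Msmo1 (log2 -1.02 ± 0.24), and 0 risers (median -0.60, adjusted p = 2.8e-05, 0.34 with an estimated correlation), with 0 fallers and a median of -0.24 under spike-in scaling. Cytochrome P450 genes had 3 risers of 23 (Cyp2e1, Cyp3a2, Cyp3a23-3a1), 4 adjusted over the list alone, and 5 fallers (Cyp3a9, Cyp2b3, Cyp2c23, Cyp3a18, Cyp17a1). The P450 median was -0.24 and 0.12 under spike-in scaling, with a mean of 0.02 and adjusted p = 0.16.

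Further after 14 days, glucose and bile acid enzymes had 5 risers of 18, such as Gys2 (log2 3.21 ± 0.25) and Cyp8b1 (log2 2.01 ± 0.29), and Pck1 down (log2 -2.29 ± 0.34). Their median was -0.08 and 0.28 under spike-in scaling, with a mean of 0.23 and adjusted p = 0.59. Amino acid and urea enzymes had Cps1, Arg1 and Tdo2 up and Hal and Kmo down (median 0.07, adjusted p = 0.68). Biliary genes had Krt23 and Sctr up and Krt19 (log2 -2.35 ± 0.22), Krt7 (log2 -2.84 ± 0.33), the water channel Aqp1 (log2 -3.45 ± 0.10) and Cldn4 (log2 -3.56 ± 0.27) down. Their median was 0.17, with a mean of -0.48 and adjusted p = 0.91. Transporters had Abcb11 up and Slc10a1 (log2 -1.41 ± 0.13) and Abcb1a down (median -0.25, 0.10 under spike-in scaling, adjusted p = 0.064). Transcription factors of hepatocytes had Nr0b2 down (median -0.15, 0.21 under spike-in scaling, adjusted p = 0.13). Progenitor genes had H19 up (log2 3.60 ± 0.46) and Afp and Itga6 down (median -0.22, 0.06 under quantile normalisation, 0.13 under spike-in scaling, adjusted p = 0.29).

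The remaining lists after 14 days did not pass the list test. TGF-β and mesenchymal genes had 2 risers of 19, Sparc among them, and 4 fallers, Tgfbi, Smad7, Tgfb1 and Pmepa1 (log2 -3.18 ± 0.32) (median -0.16, 0.20 under spike-in scaling, adjusted p = 0.28). YAP and SRF targets had 3 fallers of 17, Tagln (log2 -2.08 ± 0.40), Cnn1 and Tpm2, and 0 risers (median -0.04, 0.10 under quantile normalisation, 0.32 under spike-in scaling, adjusted p = 0.81). Wnt targets had Cdx2 down (median -0.09, 0.27 under spike-in scaling, adjusted p = 0.71). Glucocorticoid receptor targets had Mt1, Mt2A and Sult1a1 up and Sgk1 down (median 0.30, adjusted p = 0.14). Of the cell cycle genes none was called (3 at unadjusted p below 0.05, median -0.13, 0.23 under spike-in scaling, adjusted p = 0.16). Stellate and fibroblast markers had Des, Gfap and Bgn down (median -0.42, adjusted p = 0.074). Endothelial markers had Eng down (median -0.17, 0.17 under quantile normalisation, 0.19 under spike-in scaling, adjusted p = 0.44), and macrophage and leukocyte markers Cd14 down (median -0.11, 0.25 under spike-in scaling, adjusted p = 0.44).

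YAC after 14 days changed 1575 genes, 802 with normexp. Of the 1575, 589 were up and 986 down, or 37.4% up (49.1% under quantile normalisation, 67.3% under spike-in scaling). Spike-in scaling moves the median of all genes from -0.01 to 0.34. Its reference differed between the 2 arrays without YAC, where the 75th percentile stood log2 1.99 and 1.38 above the spike-in median. Alb (log2 0.01 ± 0.08, adjusted p = 0.95), Mki67 (log2 -0.05 ± 0.20, adjusted p = 0.89), Tat and Axin2 (log2 0.82 ± 0.41, adjusted p = 0.17) did not pass. Hnf4a, Epcam and Sox9 differed by less than 2-fold (log2 -0.46 ± 0.07, -0.62 ± 0.12 and 0.38 ± 0.11). Afp fell 2.14-fold (log2 -1.10 ± 0.14), which is not called under spike-in scaling (log2 -0.74, adjusted p = 0.13). The direction of 1 called gene, Col26a1, was opposite on another of its probes. After 14 days Tdo2, Sparc, Cnn1 and Cyp3a2 have adjusted p above 0.05 in at least 1 of the fits without an array. Below 2-fold are Slc10a1 and Tpm2 with normexp (log2 -0.86 and -0.69), and Idi1, Msmo1, Cdx2, Tgfbi, Apob and Cd14 under spike-in scaling (log2 -0.95, -0.66, -0.99, -0.86, -0.97 and -0.68).

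**Figure D2:**
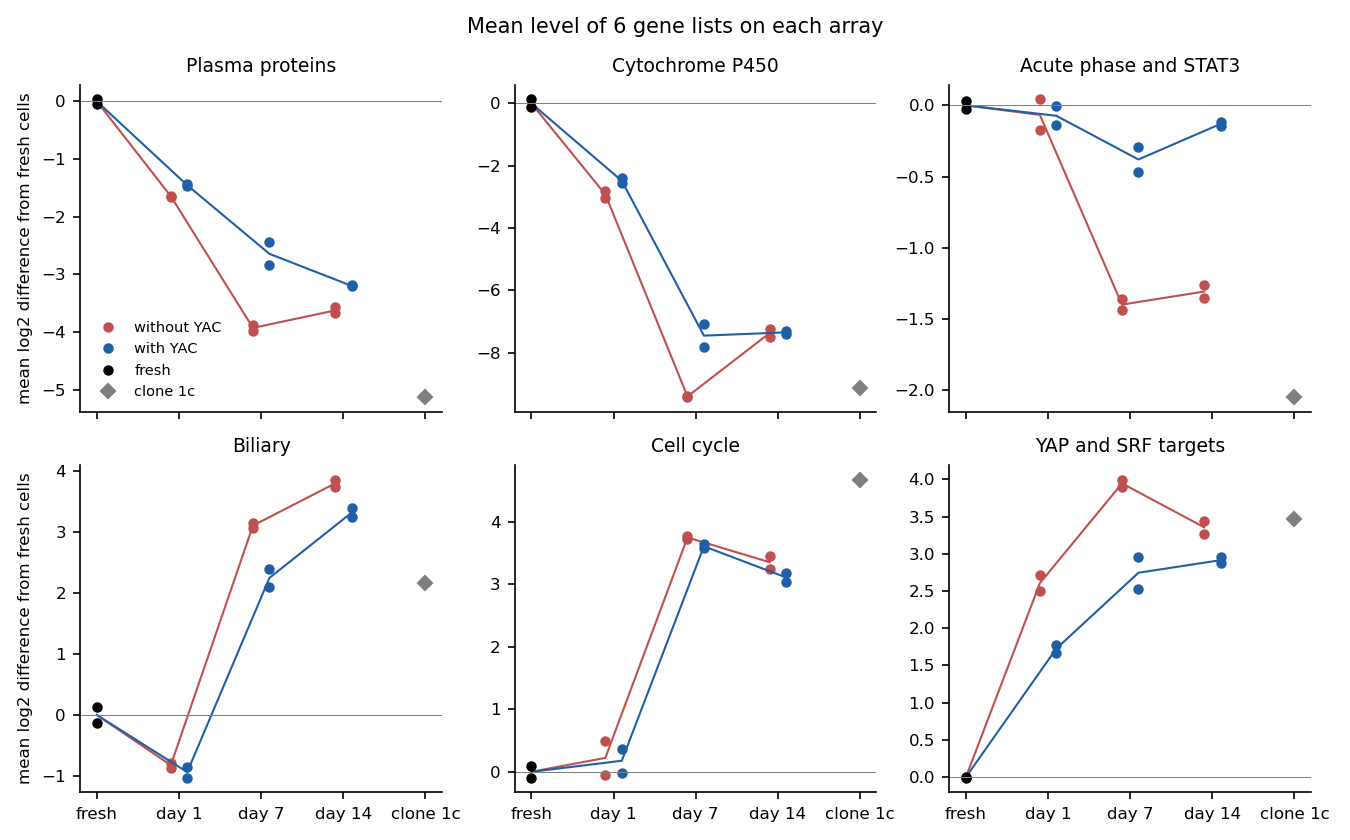
Mean log2 difference from fresh cells over the members of 6 lists for each array (points) and group means (lines): fresh cells in black, without YAC in red, with YAC in blue, clone 1c as a grey diamond.

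Day 14 with YAC against fresh cells asks how far the cultured cells have moved from the hepatocytes they came from. Large falls in liver lists include the P450 gene Cyp1a2, down at least 2168-fold (log2 -11.08 ± 0.33; n = 2 arrays per group). The bile acid transporter Slc10a1 fell 2032-fold (log2 -10.99 ± 0.13), the gluconeogenic enzyme Pck1 1845-fold (log2 -10.85 ± 0.34) and the urinary protein gene Rup2 at least 149770-fold (SE 0.22). Hnf4a fell 8.83-fold (log2 -3.14 ± 0.07) and Cebpa, another hepatocyte transcription factor, 13.8-fold (log2 -3.79 ± 0.08). Alb fell 2.15-fold (log2 -1.10 ± 0.08), but the change is -0.10 under quantile normalisation (adjusted p = 0.12) and 0.03 under spike-in scaling (adjusted p = 0.94). Among biliary and mesenchymal genes, Krt19 rose 261-fold (log2 8.03 ± 0.22), and Epcam 12.0-fold (log2 3.58 ± 0.12). Vim rose at least 1794-fold (log2 10.81 ± 0.10) and Ccn2, a matrix protein induced by YAP and TGF-β, at least 5655-fold (SE 0.16). Mki67 rose 9.60-fold (log2 3.26 ± 0.20).

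Every tested member fell in 4 liver lists. These were 20 of 20 plasma proteins (median -2.82, adjusted p = 8.3e-08, 0.27 with an estimated correlation) and 23 of 23 cytochrome P450 genes (median -6.81, adjusted p = 5.2e-09, 0.24 with an estimated correlation). So did 22 of 22 amino acid and urea enzymes (median -5.67, adjusted p = 9.6e-10, 0.24 with an estimated correlation) and 18 of 18 glucose and bile acid enzymes (median -5.20, adjusted p = 1.3e-07, 0.21 with an estimated correlation). The count of plasma proteins does not hold under quantile normalisation or spike-in scaling, where Alb is not called. Examples of falls in the 4 lists are Ambp (54.9-fold), Cyp2c7 (log2 -15.56 ± 0.26), the serine dehydratase Sds (at least 5473-fold) and Cyp7a1 (at least 844-fold). Transporters had 16 fallers of 17 and 0 risers (median -3.40, adjusted p = 9.1e-07, 0.24 with an estimated correlation). Hepatocyte transcription factors had 13 fallers of 17 and 0 risers (median -2.05, adjusted p = 0.000341, 0.21 with an estimated correlation), with 8 fallers and 3 risers under spike-in scaling. Cell cycle genes had 22 risers of 23 and 0 fallers, such as Mcm3 (18.4-fold, log2 4.20 ± 0.26) and Bub1b (18.2-fold, log2 4.18 ± 0.34) (median 3.29, adjusted p = 1.2e-08, 0.29 with an estimated correlation).

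Biliary genes had 11 risers of 16 and 1 faller (median 3.84, adjusted p = 0.00204, 0.28 with an estimated correlation). Progenitor genes had 9 risers of 13, such as Cd44 (log2 5.62 ± 0.37) and H19 (log2 4.98 ± 0.46), and 2 fallers, Afp among them (median 1.77, adjusted p = 0.0127, 0.21 with an estimated correlation). YAP and SRF targets had 11 risers of 17 and 0 fallers, Ankrd1 at least 877-fold among them (median 1.64, adjusted p = 0.000387, 0.24 with an estimated correlation). TGF-β and mesenchymal genes had 11 risers of 19, such as Itgb6 (at least 1491-fold), and 5 fallers with Snai2 (at least 50.1-fold) (median 3.02, adjusted p = 0.0294, 0.24 with an estimated correlation). That list call is absent under quantile normalisation (adjusted p = 0.073) and spike-in scaling (adjusted p = 0.12). Wnt targets had 3 risers and 7 fallers of 16, Axin2 (log2 -3.34 ± 0.41) and Notum (at least 247-fold) among the fallers (median -0.84, 0.29 under spike-in scaling, adjusted p = 0.30). Acute phase and STAT3 genes split into 5 risers, such as Lcn2 (328-fold, log2 8.36 ± 0.15), and 12 fallers, such as Crp (log2 -5.17 ± 0.34), with a median of -1.17 and adjusted p = 0.44.

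Among markers of other liver cells, down were 8 of 12 macrophage and leukocyte markers, such as Cd14 (log2 -3.53 ± 0.16) and the complement gene C1qa (log2 -2.40 ± 0.19), with 1 riser (median -1.14, adjusted p = 0.00908, 0.21 with an estimated correlation). Also down were 4 of 8 endothelial markers, such as Eng (log2 -2.40 ± 0.09), with 0 risers (median -1.32, adjusted p = 0.0371, 0.29 with an estimated correlation). Under spike-in scaling the macrophage and leukocyte list has 2 fallers and 1 riser, and the endothelial list 1 faller and 1 riser. Stellate and fibroblast markers had 3 risers and 5 fallers of 12, Reln up (at least 216-fold) and Pdgfrb down (at least 35.3-fold). Their median was -0.72, 0.12 under quantile normalisation and 0.41 under spike-in scaling, with a mean of 0.16 and adjusted p = 0.98. Glucocorticoid receptor targets had 3 risers and 10 fallers of 17 (Ddit4 up, Klf9 and Errfi1 down; median -1.76, adjusted p = 0.10). Cholesterol synthesis had 4 risers, such as Sqle (log2 2.55 ± 0.21), and 3 fallers of 18 (median 0.11, adjusted p = 0.68).

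Day 14 with YAC against fresh cells gave 8281 changed genes, 3780 up and 4501 down, or 45.6% up. That share is 87.2% under spike-in scaling, 33.6% without the filter and 32.0% with normexp. Spike-in scaling moves the median of all genes from -0.13 to 0.99, and normexp to -0.48, and the 2 groups lie on different slides. Sox9 did not pass on its brightest probe (log2 0.09 ± 0.11, adjusted p = 0.48) and rose on the mean of its probes (log2 1.45). The Sox9 values of the other comparisons also come from the brightest probe. Of 924 called genes with several detected probes, 34 had a probe called in the opposite direction, Col1a1, Cdkn1a and Cp among them.

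Fresh cells against clone 1c asks what the time in the liver changed in the transplanted cells (n = 2 arrays against 1). Fresh cells had more of the genes of a mature liver. Alb rose 64.7-fold (log2 6.02 ± 0.10), Hnf4a 11.3-fold (log2 3.50 ± 0.08), Cyp1a2 at least 2190-fold (log2 11.10 ± 0.41) and Cps1 at least 9450-fold (log2 13.21 ± 0.65). Of genes active in fetal liver, Afp fell 8.83-fold (log2 -3.14 ± 0.18), the growth factor Igf2 168-fold (log2 -7.39 ± 0.23) and the noncoding RNA H19 437-fold (log2 -8.77 ± 0.56). Krt19 fell 70.5-fold (log2 -6.14 ± 0.27), the matrix protein Spp1 405-fold (log2 -8.66 ± 0.36) and Vim at least 2758-fold (log2 -11.43 ± 0.12). Mki67 fell 24.1-fold (log2 -4.59 ± 0.24). The largest rises were Rup2 (at least 303250-fold, SE 0.27) and Mug1, a plasma protease inhibitor (at least 260990-fold), and the largest fall was Bex1 (at least 11857-fold).

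All tested members of 4 liver lists rose. Up were 20 of 20 plasma proteins (median 4.61, adjusted p = 5.2e-09, 0.24 with an estimated correlation) and 23 of 23 cytochrome P450 genes (median 9.27, adjusted p = 1.5e-09, 0.24 with an estimated correlation). Likewise up were 22 of 22 amino acid and urea enzymes (median 6.65, adjusted p = 9.5e-10, 0.24 with an estimated correlation) and 18 of 18 glucose and bile acid enzymes (median 7.80, adjusted p = 2.7e-08, 0.21 with an estimated correlation). F9 (at least 3341-fold), Tdo2 (5769-fold), Pck1 (at least 65442-fold) and Slc27a5 (17851-fold) are examples. Transporters had 16 risers of 17, such as Abcb11 (at least 7267-fold), and 0 fallers (median 5.04, adjusted p = 2.7e-07, 0.23 with an estimated correlation). Hepatocyte transcription factors had 13 risers of 17 and 0 fallers (median 2.80, adjusted p = 5.4e-05, 0.21 with an estimated correlation). Acute phase and STAT3 genes had 15 risers of 20, such as Saa4 (794-fold, log2 9.63 ± 0.30), and 3 fallers (median 2.07, adjusted p = 0.0139, 0.28 with an estimated correlation). Glucocorticoid receptor targets had 12 risers of 17 and 2 fallers (median 2.01, adjusted p = 0.0137, 0.21 with an estimated correlation).

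Cell cycle genes fell in full, 23 of 23 (Ccna2 at log2 -5.92 ± 0.34, Plk1 at log2 -5.67 ± 0.22; median -4.82, adjusted p = 2.6e-09, 0.28 with an estimated correlation). YAP and SRF targets had 13 fallers of 17, such as Ccn2 (at least 1522-fold) and Ankrd1 (at least 1231-fold), and 1 riser (median -2.39, adjusted p = 8.7e-05, 0.24 with an estimated correlation). Progenitor genes had 8 fallers of 13 and 1 riser (median -2.63, adjusted p = 0.00143, 0.21 with an estimated correlation). Biliary genes had 9 fallers of 16 and 3 risers (median -2.20, adjusted p = 0.052). TGF-β and mesenchymal genes had 10 fallers of 19, such as Sparc (log2 -8.32 ± 0.54), and 6 risers (median -1.09, adjusted p = 0.11). Wnt targets had 3 risers, Notum (35.5-fold) among them, and 6 fallers of 16, 5 adjusted over the list alone, Nkd1 (242-fold) among them (median -0.63, adjusted p = 0.52). Cholesterol synthesis had 9 fallers of 18, such as Sqle (log2 -2.91 ± 0.26), and 2 risers (median -0.91, adjusted p = 0.075).

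Markers of other liver cells were higher in fresh cells than in clone 1c for 6 of 8 endothelial markers, such as Eng (15.5-fold, log2 3.96 ± 0.12) and Pecam1 (at least 6.15-fold), with 0 lower (median 1.51, adjusted p = 0.021, 0.28 with an estimated correlation). For macrophage and leukocyte markers 8 of 12 rose, such as Cd14 (25.4-fold, log2 4.67 ± 0.20) and C1qa (log2 2.45 ± 0.23), and 0 fell (median 1.19, -0.09 under spike-in scaling, adjusted p = 0.0127, 0.21 with an estimated correlation). Under spike-in scaling the risers are 2 in each of these lists. Stellate and fibroblast markers had 8 fallers of 12, such as the proteoglycan gene Dcn (at least 65.7-fold), and 1 riser, Rgs5 (at least 37.7-fold) (median -1.61, adjusted p = 0.0336, 0.30 with an estimated correlation).

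Fresh cells against clone 1c gave 9654 changed genes, 5226 up and 4428 down, or 54.1% up. That share is 14.8% under spike-in scaling, 66.8% without the filter and 72.3% with normexp. Spike-in scaling moves the median of all genes from 0.11 to -1.17, and normexp to 0.58. Sox9 on its brightest probe (log2 0.83 ± 0.13) and Epcam (log2 -0.72 ± 0.15) differed by less than 2-fold. Axin2 fell 2.56-fold (log2 -1.36 ± 0.50), a call lost without replicate 1 of the fresh cells (log2 -0.74, adjusted p = 0.15). Of 1071 called genes with several detected probes, 46 had a probe called in the opposite direction.

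Day 14 with YAC against clone 1c asks whether the cultured cells return to the state of the clone they came from. Several liver genes were higher in the cultured cells than in clone 1c. Alb was 30.2-fold higher (log2 4.91 ± 0.10) and the lipolysis inhibitor G0s2 1593-fold (log2 10.64 ± 0.20; n = 2 arrays against 1). Abcb11 was higher at least 212-fold (log2 7.73 ± 0.29) and A2m, a plasma protease inhibitor, 364-fold (log2 8.51 ± 0.55). Igf2, Afp and H19, active in fetal liver, were lower, Igf2 71.5-fold (log2 -6.16 ± 0.23), Afp 25.3-fold (log2 -4.66 ± 0.18) and H19 13.9-fold (log2 -3.79 ± 0.56). Epcam, an epithelial adhesion gene, rose 7.28-fold (log2 2.86 ± 0.15) and the bile duct keratin Krt19 3.71-fold (log2 1.89 ± 0.27). Mki67 fell 2.51-fold (log2 -1.33 ± 0.24), Axin2 25.9-fold (log2 -4.70 ± 0.50), and the mucin-type protein gene Pdpn at least 9515-fold (SE 0.39). Hnf4a was higher by less than 2-fold (log2 0.36 ± 0.08, adjusted p = 0.0075).

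Liver lists were higher throughout. Of the plasma proteins 14 of 20 rose and 0 fell (median 1.54, adjusted p = 7e-09, 0.24 with an estimated correlation). Of glucose and bile acid enzymes 12 of 18 rose and 0 fell (median 2.17, adjusted p = 7.4e-07, 0.21 with an estimated correlation). Of cytochrome P450 genes 11 of 23 rose and 1 fell (Cyp4a3 up 90.0-fold; median 1.25, adjusted p = 0.000133, 0.35 with an estimated correlation). Of transporters 8 of 17 rose and 1 fell (median 0.79, adjusted p = 0.00176, 0.32 with an estimated correlation). Of amino acid and urea enzymes 9 of 22 rose and 0 fell (median 0.83, adjusted p = 0.00329, 0.47 with an estimated correlation). Of hepatocyte transcription factors 7 of 17 rose and 0 fell (Nr1i3 at log2 2.32 ± 0.16; median 0.43, adjusted p = 0.00233, 0.24 with an estimated correlation). Acute phase and STAT3 genes had 11 risers of 20 and 1 faller (Saa4 at log2 6.81 ± 0.30; median 1.38, adjusted p = 7.8e-05, 0.21 with an estimated correlation). Biliary genes had 9 risers of 16 and 2 fallers, Spp1 (log2 -3.03 ± 0.36) among these (median 1.26, adjusted p = 0.00622, 0.31 with an estimated correlation). Day 14 cells without YAC, not tested against clone 1c, also had higher means of these lists than clone 1c. Relative to fresh cells the cytochrome P450 mean was -7.37 without YAC, -7.35 with YAC and -9.14 in clone 1c. For plasma proteins the means were -3.62, -3.20 and -5.13.

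Cell cycle genes had 22 fallers of 23 (Cdc20 at log2 -2.03 ± 0.16; median -1.47, adjusted p = 2e-08, 0.29 with an estimated correlation). Cholesterol synthesis had 7 fallers of 18 and 0 risers, such as Mvd at log2 -1.38 ± 0.28 (median -0.89, adjusted p = 0.00204, 0.44 with an estimated correlation). Stellate and fibroblast markers had 6 fallers of 12 and 1 riser, Dcn down at least 129-fold (median -0.93, adjusted p = 0.00864, 0.25 with an estimated correlation). Not passing were progenitor genes (3 risers, 5 fallers of 13; adjusted p = 0.43), Wnt targets (1 and 7 of 16; adjusted p = 0.083), YAP and SRF targets (1 and 4 of 17; adjusted p = 0.33), glucocorticoid receptor targets (5 and 1 of 17; adjusted p = 0.092) and endothelial markers (1 and 0 of 8; adjusted p = 0.13). TGF-β and mesenchymal genes had 5 risers and 2 fallers of 19 (median 0.09, -0.07 under spike-in scaling, adjusted p = 0.53), and macrophage and leukocyte markers 2 risers and 0 fallers of 12 (median 0.07, -0.06 under quantile normalisation, -0.09 under spike-in scaling, adjusted p = 0.43).

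Day 14 with YAC against clone 1c gave 3679 changed genes, 2111 up and 1568 down, or 57.4% up and 46.3% under spike-in scaling, which moves the median of all genes from 0.01 to -0.14. Tat rose 2.13-fold (log2 1.09 ± 0.27), below 2-fold under quantile normalisation (log2 0.97). Sox9 on its brightest probe was higher by less than 2-fold (log2 0.92 ± 0.13), and Cyp1a2 was dim in both groups. The 2 groups lie on different slides, and 1 called gene, Kcnn4, had another probe called in the opposite direction.

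**Figure D3:**
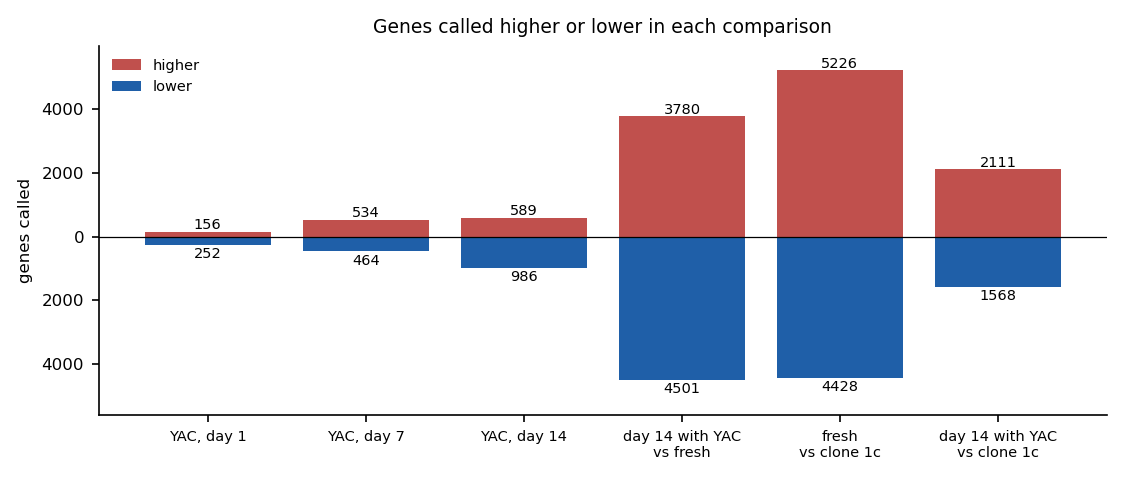
Number of genes that rose and fell in each of the 6 comparisons (limma, adjusted p < 0.05 and at least 2-fold).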

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

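The differences of the YAC effect between days, and the tests of background floor and array scaling for the cytochrome P450 genes, were chosen only after the results were seen, while the leave-out test was planned. No list difference between days passed with an estimated correlation, where the lowest adjusted p was 0.37.

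Between day 1 and day 7 the YAC effect became more positive for plasma proteins, by a median of 0.83 (0.54 under spike-in scaling; 8 genes more positive, 0 more negative; adjusted p from 0.37 to 0.64 with an estimated correlation for these lists). The median difference was 0.65 for cytochrome P450 genes (0.36 under spike-in scaling; 8 and 3) and 0.44 for acute phase and STAT3 genes (0.15 under spike-in scaling; 6 and 1). Cholesterol synthesis moved by -0.52 (-0.80 under spike-in scaling; 0 and 1) and hepatocyte transcription factors by -0.24 (-0.53 under spike-in scaling; 1 and 3). The effect on Afp moved by -1.12 ± 0.20 (adjusted p = 0.00921 in limma). Krt19 was well above background in neither day 1 group, so no difference from day 1 is given for it. In all, 852 genes had another YAC effect on day 7 than on day 1 (640 to 883 with 1 array left out), 486 more positive and 366 more negative. Under spike-in scaling there are 356, and the balance turns to 128 more positive and 228 more negative.

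Between day 1 and day 14 the YAC effect on cholesterol synthesis became more negative, by a median of -1.14 (0 genes more positive, 10 more negative; -0.84 with 0 and 0 under spike-in scaling; adjusted p from 0.37 to 0.64 with an estimated correlation for these lists). The median difference was -0.70 for transporters (-0.41 under spike-in scaling; 1 and 7), -0.64 for hepatocyte transcription factors (-0.34 under spike-in scaling; 0 and 5) and -0.44 for cytochrome P450 genes (-0.14 under spike-in scaling; 2 and 7). YAP and SRF targets moved by 0.54 (0.84 under spike-in scaling; 5 and 0) and acute phase and STAT3 genes by 0.41 (0.71 under spike-in scaling; 8 and 2). Hnf4a moved by -1.06 ± 0.10 and Afp by -1.25 ± 0.20, each with adjusted p below 0.05 in limma. The count was 1617 genes (1368 to 1549 with 1 array left out), 654 more positive and 963 more negative. Under spike-in scaling it is 806, with 461 more positive and 345 more negative.

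Between day 7 and day 14 the YAC effect on cytochrome P450 genes became more negative, by a median of -1.34 (-0.75 under spike-in scaling; 0 genes more positive, 11 more negative; adjusted p from 0.37 to 0.56 with an estimated correlation for these lists). Other liver lists moved the same way by less, and stood nearer to 0 under spike-in scaling. These were transporters at -0.83 (-0.25 under spike-in scaling; 0 and 8), amino acid and urea enzymes at -0.82 (-0.23; 0 and 4), glucose and bile acid enzymes at -0.74 (-0.15; 0 and 3) and plasma proteins at -0.66 (-0.07; 0 and 6). Cholesterol synthesis moved by -0.66 (-0.07 under spike-in scaling; 0 and 1) and hepatocyte transcription factors by -0.24, or 0.34 under spike-in scaling (0 and 1). Biliary genes moved by 0.50 (1.08 under spike-in scaling; 2 and 1) and YAP and SRF targets by 0.67 (1.26 under spike-in scaling; 4 and 0). The count was 955 genes (592 to 944 with 1 array left out), 337 more positive and 618 more negative. Under spike-in scaling it is 507, and the balance turns to 352 more positive and 155 more negative. The spike-in reference differs between the 2 day 14 arrays without YAC.

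The smaller YAC effect on cytochrome P450 genes at day 14 than at day 7 goes with higher levels without YAC. Relative to fresh cells the list mean without YAC was -9.41 (SD 0.03) at day 7 and -7.37 (SD 0.18) at day 14, and with YAC -7.45 (SD 0.52) and -7.35 (SD 0.08), a change of 2.04 without and 0.11 with YAC (1.67 and 0.32 under spike-in scaling). Against a background floor at day 7 without YAC, 1 of the 11 members that fell was below background on both of those arrays, and a floor there would make the day 7 effect look smaller. Against array scaling, the median difference is -0.75 under spike-in scaling, although only 4 members then fall and the spike-in reference differs between replicate arrays. Against 1 odd array, 8 to 14 members fall when each array is left out. Why the levels without YAC were higher at day 14 stays open, since 2 arrays per group may not separate time from differences between cultures.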

How the results depend on the processing

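All settings named here were planned except spike-in scaling and the crossed replicate block, which were chosen only after the results were seen.

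With normexp 200, 606 and 802 genes pass for YAC after 1, 7 and 14 days, of which 183, 594 and 748 are among the 408, 998 and 1575 called otherwise. Spike-in scaling gives 244 genes after 1 day, 234 of them among the 408. Without the 2-fold cut, adjusted p passes 1641, 4183 and 5915 genes with normexp, against 1681, 3870 and 5712 otherwise. The loss with normexp therefore lies mainly in the 2-fold cut. Under spike-in scaling adjusted p alone passes 244 genes after 1 day against 1681, so there the loss lies in the p-values. Why the folds or the p-values changed was not tested. Alb in day 14 with YAC against fresh chimera hepatocytes is 0.026 under spike-in scaling against -1.10. That scaling shifts all genes alike, and their median moves from -0.13 to 0.99. Tnfrsf19 in fresh chimera hepatocytes against clone 1c is 0.54 with normexp against -2.43, and the cause was not tested. The cell cycle list after 1 day has a mean log2 change of 0.22 (adjusted p = 0.047) without replicate 2 of the cells without YAC and -0.32 without replicate 1, against -0.05 with all arrays, so its sign rests on 1 array. Leaving out an array gives 334 to 565, 761 to 1070 and 1277 to 1571 genes for YAC after 1, 7 and 14 days. For day 14 with YAC against fresh cells it gives 8151 to 8310, for fresh cells against clone 1c 9402 to 9712, and for day 14 with YAC against clone 1c 3535 to 3725, where clone 1c itself cannot be left out. Of 460 gene results 371 were the same in every setting, as were 85 of 108 list results.

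A replicate block gives 408, 992 and 1568 genes for the YAC comparisons, and a crossed block 1535 after 14 days. Correlations of replicate differences were 0.18, 0.0894 and -0.114 for days 1, 7 and 14, and 0.116 and 0.126 between fresh cells and day 1 cells without and with YAC. Day 1 cells without YAC had larger ones of both signs, 0.248 against day 14 with YAC and -0.230 against day 14 without YAC. The labels do not show that equal replicate numbers pair.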

Other observations

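The tests on markers of other liver cells were chosen only after the results were seen, as were the stomach and gut genes and the course of Igf1, while the prediction for hormone-dependent genes was written before its test genes were looked at.

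Some genes known from stomach and gut epithelium were chosen after their values were seen, and no list of such genes was tested. Levels are log2 relative to the array's 75th percentile. Krt20, an intestinal keratin, stood at -6.80 in fresh cells, 6.48 after 14 days without YAC and 3.99 with YAC (5.61-fold lower with YAC, log2 -2.49 ± 0.13, n = 2 arrays per group). Lgals4, a lectin of gut epithelium, stood at -7.81, 5.45 and 0.48 (31.4-fold lower with YAC, log2 -4.97 ± 0.19), and the trefoil factor Tff1 at -7.29, 3.00 and -4.12. Others were far above fresh cells in both conditions without passing for YAC at day 14: Ctse at -7.97, 3.04 and 3.01 (log2 -0.03, adjusted p = 0.84) and Vil1 at -6.83, 1.08 and 0.07 (log2 -1.01, adjusted p = 0.053). The YAC effect moved from day 7 to day 14 by -4.87 ± 0.91 for Tff1, -2.93 ± 0.26 for Lgals4 and -1.18 ± 0.18 for Krt20. It did not pass for Cdx2 (-0.38 ± 0.21, adjusted p = 0.30), Tff3 (0.81 ± 0.26, adjusted p = 0.088) or Vil1 (0.80 ± 0.47, adjusted p = 0.33).

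Igf1, the main growth factor released by the liver, was at 8.21 in fresh cells and at 1.34 with YAC and -6.08 without YAC after 14 days. Its YAC effect was -0.23 ± 0.15 after 1 day (adjusted p = 0.41), 4.69 ± 0.15 after 7 days (25.8-fold) and 7.42 ± 0.15 after 14 days (171-fold). The increase of the effect from day 7 to day 14 was 2.73 ± 0.21 (adjusted p = 0.000312). After 7 days the level was 1.74 with YAC and -2.95 without YAC. The larger effect at day 14 therefore goes with a further fall without YAC, as the level with YAC did not rise.

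Markers of endothelium and of macrophages and leukocytes were higher in fresh cells than in clone 1c, with 14 of the 20 markers tested up and 0 down. RNA of other liver cells in the fresh preparation could give this, but that count only restates the pattern, and the later fall of 12 markers by day 14 with YAC uses the same fresh arrays and differs in slide. The tables also hold 19 of the 20 markers well above background in clone 1c and 15 on both day 14 arrays with YAC. Spike-in scaling lowers the marker median from 1.27 to -0.017 by shifting all genes alike, so the rise itself depends on the scaling. The markers stand 1.15 above the median of all genes under either scaling, because a shift of all genes cannot change that gap. The gap lies within the SD of 1.21 over the markers, but that SD is a spread between genes. This test therefore cannot decide on array scaling. Host cells, hepatocyte expression and cross-hybridisation stay open.

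Male-predominant liver genes were higher in replicate 1 than in replicate 2 of fresh and day 1 cells, by a mean of 1.41, 1.43 and 1.56 in fresh cells and in day 1 cells without and with YAC (5 genes). On day 7 their mean difference was 0.07 without and -0.62 with YAC, and on day 14 -0.05 without and 0.17 with YAC. If replicates came from separate host animals or preparations with another hormone setting, unseen male genes should be higher and unseen female genes lower in replicate 1, and 4 of 6 signs were met. The rule written beforehand required all 6, so the prediction was not met. The 6 unseen male genes had means of 0.87 (SD 0.52), 0.72 (SD 0.69) and 0.64 (SD 0.75), and the 6 unseen female genes 0.16 (SD 0.31), -0.06 (SD 0.31) and 0.01 (SD 0.17). The unseen female genes had means above 0 in fresh cells and in day 1 cells with YAC, within their SD. Replicate number coincides with the position on the slide in these groups. Whether replicates are separate animals or shared preparations stays open. Only the male genes had a mean with the predicted sign in each fresh and day 1 group. Among the 6 unseen male genes, Car3, Cyp4a2, Hsd3b5 and Mup4 were higher in replicate 1 in each of these groups. Cyp2a2 was lower in each (-0.14 in fresh cells, -0.07 and -0.24 in day 1 cells without and with YAC). Bcl6 was higher in fresh cells and lower on day 1 (-0.05 without and -0.10 with YAC).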
